A study of Mus musculus with 4 samples.

How the data were processed

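The data are assays of transposase-accessible chromatin (ATAC-seq) on neurospheres, free-floating clusters of neural progenitor cells, grown from the hippocampus of newborn C57BL/6 mice. Per the labels' protocols, the dissociated cells were cultured for 7 days with FGF2 and EGF at 20 ng/ml each. All 4 cultures carried the hGFAP-Cre transgene. The 2 control cultures had an intact Fgf13 gene and the 2 Fgf13cko cultures a floxed Fgf13 gene on the X chromosome, per the labels. Groups and replicate numbers were taken from the sample titles. The cells of 1 mouse filled 2 culture wells, and the labels do not say whether the cultures of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical.

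The authors deposited a table for 29121 merged regions and 1 list of peaks per sample. Per the file headers, the table holds estimated counts, raw tag counts that HOMER assigned to each merged broad peak on mm10 without normalisation. The submitters' processing notes name Bowtie2, Picard, MACS2, DESeq2 and HOMER, with no role or order. The versions, the shift of reads for the transposase and the handling of duplicates are not given in the sources used here. Every deposited count is a multiple of 0.5, and 50.2% of the values are whole. The estimated counts were rounded to whole numbers before any test. The 29121 regions are exactly those formed when the peak lists are merged and regions with a peak in all 4 samples are kept, and each start and end in the table equals a peak's start and end. A region open in 1 group only is therefore outside the count table. In the table, 82 regions hold 0 tags in all 4 libraries. In the peak lists, each peak's -log10 p and -log10 q, its fold enrichment over the local background (a ratio) and its score are the authors' own values, per the column order of the deposited lists. They were used only to describe or filter peaks within a list. The lowest -log10 q of the lists lay between 1.00 and 1.01.

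The tag totals in the file header were 24.9 and 26.0 M for control 1 and 2, and 16.8 and 13.1 M for Fgf13cko 1 and 2. The regions held 8.60, 10.3, 4.15 and 3.84 M of these tags. A pair of mitochondrial regions took 67.7% and 68.4% of the region tags in the controls, against 38.5% and 31.5% in Fgf13cko. The nuclear regions held 2.78, 3.25, 2.55 and 2.63 M tags, with a median of 63 and 72 tags per region in the controls and 57 and 65.5 in Fgf13cko. Across regions, log2 counts correlated at r = 0.960 between the controls, 0.881 between the Fgf13cko libraries and 0.806 to 0.846 between groups. The chi-square statistic per region was 1.69 between the controls and 5.61 between the Fgf13cko libraries, so neither pair agreed within sampling noise and none was merged.

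Accessibility was compared with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided), with TMM scaling, filterByExpr on the groups and Benjamini-Hochberg adjustment, at a threshold of 0.05. All 4 libraries entered the fit without covariates. The mitochondrial regions name no gene and entered the region fit only. Promoter counts were summed per gene over regions that overlap 1 kb on each side of the nearest start site given in the table. Distal counts were summed per gene over the other regions within 100 kb of that site. The plan had been to use every start site of a gene, but the nearest site given in the table was used, so a region shared by neighbouring genes counts for 1 of them. Region coordinates are those of the table, on mm10, and gene coordinates come from a RefSeq table of GRCm38.p6. Normalised counts are tag counts divided by the relative effective library size. The common biological coefficient of variation was 0.191 for regions, 0.127 for promoters and 0.178 for distal sums.

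Before the data were examined, 23 gene lists with 478 genes were fixed, of which 309 genes had a tested promoter and 245 a tested distal sum. The lists covered stem cell, neurogenic, neuronal, GABAergic, glial and other cell-type markers, the BAF complex, Notch, Wnt, FGF, sodium channel, microtubule, patterning, HOX, stress, apoptosis, cell cycle and housekeeping genes. The HOX list had 0 measured members and was not tested, which left 22 lists. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. With an estimated correlation, camera takes its degrees of freedom from the residuals of only 4 libraries and has little power. A list that fails there is therefore not shown to owe its call to correlation between genes. The genes named were fixed by rule: the 10 regions, and the 10 promoters, with the largest rise and with the largest fall past the threshold whose Fgf13cko values lay on 1 side of both controls. Each gene was taken once, and predicted genes were skipped. From each list described, up to 4 members with the smallest p were eligible. Fgf13, Arid1b, Neurod1, Sox2, Hes5, Dcx, Gfap, Olig2 and Mki67 were always to be given. No region of the tested tables was assigned to Dcx. Results for some list members are not reported here.

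The steps were tested on simulated counts drawn from the real means and library sizes, with 200 changed features. Features were drawn independently, with the same dispersion trend in both groups. The simulation therefore holds neither the wider spread of the Fgf13cko pair nor correlation between genes. Its false shares and its list result need not carry over to the real data. In the region step (29121 regions), 33% of 2-fold and 88% of 4-fold changes were recovered, and 3 of 124 calls were false. In the promoter step (11355 genes), 67% and 100% were recovered, and 3 of 170 calls were false. In the distal step (7760 genes), 51% and 95% were recovered, and 6 of 152 calls were false. A list of 20 genes raised 1.5-fold was called at an adjusted p of 4.51e-24, with 0 of the other lists. Peak lists were compared with bedtools 2.31.1, with an overlap of at least 1 bp.

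The alternatives were DESeq2 size factors, library size only, a loess offset on abundance, no filter, a mean of at least 50 counts, the Wald test of DESeq2 1.42.0, limma-voom, a threshold of 0.01, the replicate number as a block, each library left out in turn, autosomes only, a promoter window of 3 kb and a distal limit of 20 kb. For peak lists they were a -log10 q of at least 5 and an overlap of 50% of both peaks. Fits without the mitochondrial regions, without chromosome 7 and without chromosome 7 from 80 Mb were chosen after seeing the data. Motif words in changed regions were not analysed here, since no genome sequence was used.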

Results

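Accessible chromatin was measured in hippocampal neurospheres of newborn mice, in 2 control cultures and 2 cultures with a conditional deletion of Fgf13 (Fgf13cko). Fgf13 encodes an intracellular FGF family protein that binds sodium channels and microtubules and is not secreted. The design compares the accessibility of the same regions with and without the gene. The nuclear regions held between 2.55 and 3.25 M tags per library. The mitochondrial share of all tags differed by group, at 23.4% and 27.0% in the controls and 9.54% and 9.19% in Fgf13cko.

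The targeted gene itself showed no region past the threshold. Fgf13 lies on chromosome X from 59062139 to 59585572, and 4 measured regions were assigned to it. The promoter region at 59133646 to 59135567 held a normalised count of 87.7 ± 1.36 (SD, n = 2) in controls and 77.8 ± 14.0 in Fgf13cko (log2 fold change -0.18, adjusted p = 0.705). The region of the other start site, in the 5' UTR at 59566138 to 59568294, held 102 ± 2.19 and 104 ± 31.9 (log2 fold change 0.03, adjusted p = 0.960). The intronic region at 59178885 to 59179789 had 48.8 ± 10.4 in controls and 87.4 ± 3.60 in Fgf13cko (log2 fold change 0.83, adjusted p = 0.0848), and the intronic region at 59241102 to 59241909 had 55.6 ± 14.8 and 38.3 ± 4.60 (log2 fold change -0.53, adjusted p = 0.375). The labels do not say which exon is floxed, so these regions may lie outside the deleted part and do not check the genotype labels. The intronic region at 59178885 had a log2 fold change of 0.64 without control replicate 1 and 1.08 without control replicate 2. It had 0.76 without Fgf13cko replicate 1 and 0.86 without Fgf13cko replicate 2. In the DESeq2 Wald test it did not pass (adjusted p = 0.304). With library size as the only scaling it passed in edgeR (1.80, adjusted p = 0.000906), as did both regions at start sites (0.78 and 0.98, adjusted p = 0.0149 and 0.00508). On chromosome X, 17 of 694 tested regions rose and 5 fell.

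Among single regions, the largest named rise was in an intronic region nearest to Adgra1, an adhesion G protein-coupled receptor gene (chromosome 7, 139849996 to 139850765). This region went from 32.7 ± 15.0 to 236 ± 43.1 (n = 2 each, log2 fold change 2.87, SE 0.30, adjusted p = 0.00385). It was followed by intronic regions nearest to Fam212b (2.79) and to Pvt1, a long non-coding RNA gene beside Myc (2.65). Those nearest to Npnt, which encodes the matrix protein nephronectin (2.62), and to Mgat5, a glycosyltransferase gene (2.59), came next. Intronic regions nearest to Rnf122 (2.55), to Tnc, which encodes the radial glial matrix protein tenascin C (2.53, chromosome 4, 64002077 to 64002884), and to Tex14 (2.52) also rose. Intergenic regions nearest to Vash1 (2.52) and to Nptx1, the neuronal pentraxin 1 gene (2.50), rose as well. At the region nearest to Tnc the count went from 31.0 ± 7.74 in controls to 179 ± 14.5 in Fgf13cko (adjusted p = 0.00384). The Adgra1 region lies on the distal part of chromosome 7, which shifted upwards as a whole.

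The largest named fall was in an intronic region nearest to Shisa2, a gene for an antagonist of Wnt and FGF receptor maturation, from 222 ± 35.1 to 30.5 ± 2.58 (n = 2 each, log2 fold change -2.86, SE 0.23, adjusted p = 0.00384; chromosome 14, 59736905 to 59737681). The region nearest to Lmo4, a LIM-only transcriptional cofactor gene (-2.81), fell too. So did intronic regions nearest to Itgb2l (-2.59), to the zinc transporter gene Slc39a10 (-2.51) and to the kinase gene Stk39 (-2.43). The gene named is that of the nearest start site, which need not hold the intron. Intergenic regions nearest to Nfkbiz, an NF-kB cofactor gene (-2.45), Syf2 (-2.42), the serine synthesis gene Psat1 (-2.40), Mir680-3 (-2.34) and Lpp (-2.32) completed the list. The fallen regions were low in Fgf13cko, with mean counts between 13.2 at Nfkbiz and 48.1 at Slc39a10.

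**Figure D1:**
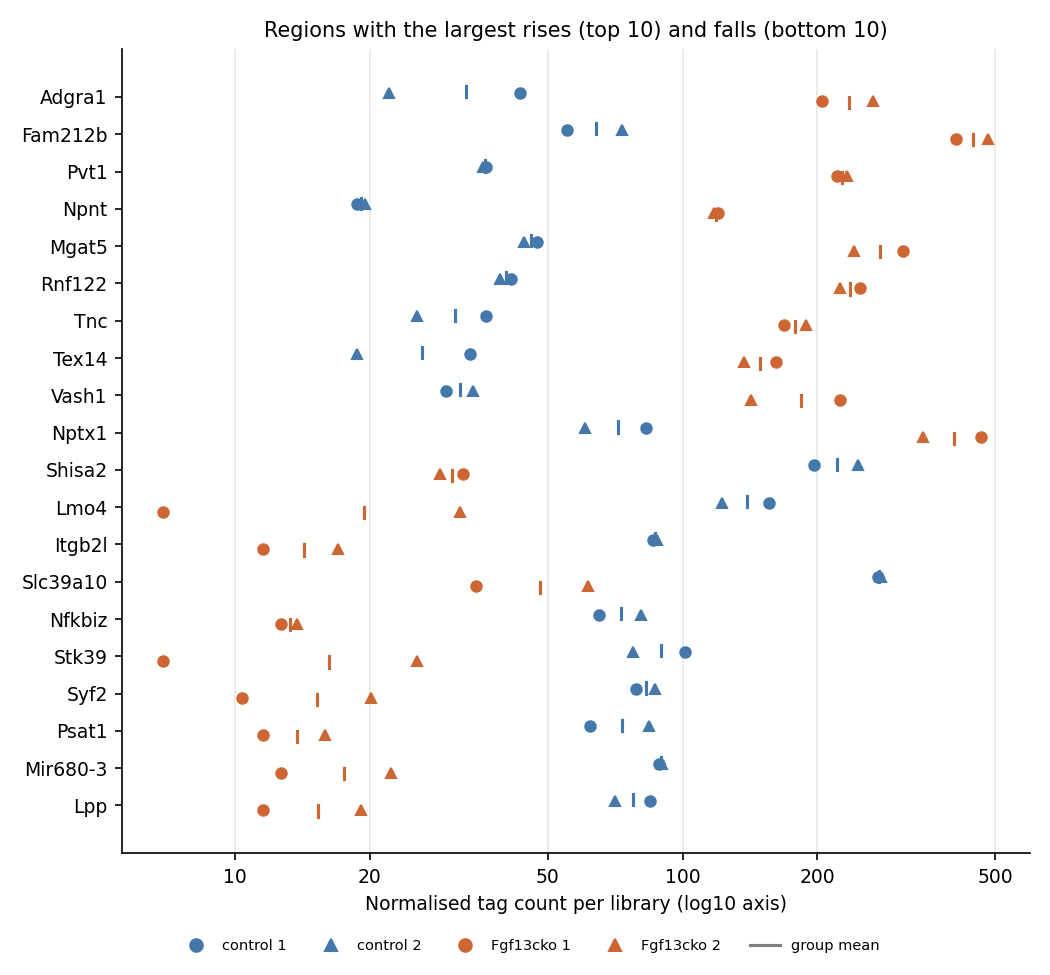
Normalised tag count per library (log10 axis) at the 20 named regions, by nearest gene, with the group mean as a bar. Control values are blue and Fgf13cko values orange, from Adgra1 (32.7 against 236) to Lpp (77.7 against 15.3). The groups do not overlap at any of these regions because the rule that named them required it.

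Over all 28801 tested regions, 1786 rose and 472 fell in Fgf13cko, so 79.1% of the changed regions rose. With a loess offset on abundance, 2134 rose and 1096 fell, a share of 66.1%. With library size as the only scaling, the median log2 fold change of all regions moved to 0.97 and 17644 rose, since the mitochondrial tags then set the scale. The counts depended on which library was left out: 485 regions passed without control replicate 1, 224 without control replicate 2, 7000 without Fgf13cko replicate 1 and 10086 without Fgf13cko replicate 2, with rising shares of 85.8%, 85.7%, 58.9% and 50.6%.

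At promoters, the largest rises were at BC064078 (log2 fold change 1.81), Tex14 (1.75), Rdm1 (1.69), the microtubule plus-end gene Clip1 (1.67), Mir1936 (1.64) and Ghrh, which encodes growth hormone releasing hormone (1.64). Scarna6 (1.58), the GABA-A receptor subunit gene Gabrg1 (1.57), Sel1l3 (1.55) and the interferon-induced gene Ifi44l (1.51) followed. The promoter of Gabrg1 (gene on chromosome 5, 70751047 to 70842617) went from 114 ± 0.709 to 340 ± 16.5 (n = 2 each, SE 0.15, adjusted p = 0.00151). The largest falls were at the urea transporter gene Slc14a1 (-1.90), Ccdc190 (-1.57), Serpina3n, a protease inhibitor gene induced in reactive astrocytes (-1.56), Lgals12 (-1.35) and Sbno2 (-1.22). Falls at Apoc1, an apolipoprotein gene (-1.22), the receptor tyrosine kinase gene Axl (-1.19), Taf7 (-1.18), Bend3 (-1.15) and Fam84b (-1.15) were next in size. The promoter of Serpina3n (gene on chromosome 12, 104406646 to 104414334) went from 136 ± 8.89 to 46.1 ± 7.92 (SE 0.21, adjusted p = 0.00518).

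Of 11306 tested promoters, 242 rose and 68 fell. With a loess offset 482 promoters changed, with a mean of at least 50 counts 491, and in the DESeq2 Wald test 142. Leaving out either control ended every edgeR call (0 promoters, with 858 at an unadjusted p under 0.05 without control replicate 1 and 850 without control replicate 2, where the Wald test called 4 and 17 and limma-voom 0), while 1185 passed without Fgf13cko replicate 1 (685 rose, 500 fell) and 2810 without Fgf13cko replicate 2 (1397 rose, 1413 fell).

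Neuronal genes were among the promoters that rose. In the list of synaptic and mature excitatory neuron genes, 2 of 14 measured promoters rose and 0 fell (4 and 0 adjusted over the list alone), and 12 of 14 had a higher mean in Fgf13cko. Camk2a, a synaptic kinase gene, went from 49.8 ± 0.0827 to 132 ± 2.34 (n = 2 each, log2 fold change 1.40, SE 0.20, adjusted p = 0.00618), and Syt1, which encodes a calcium sensor of synaptic vesicles, from 104 ± 7.67 to 199 ± 17.6 (0.94, adjusted p = 0.0154). Grin2a (0.75, adjusted p = 0.0995) and Snap25 (0.57, adjusted p = 0.112) did not pass. The list as a whole lay above the other genes in camera (adjusted p = 0.00288). It also did in camera with a loess offset (adjusted p = 0.00780) and with the replicate number as a block (adjusted p = 0.00315). With an estimated correlation the list did not pass (adjusted p = 0.749), in a version with little power at 4 libraries. In fry, which tests the list against no change and not against the other genes, it did not pass either (adjusted p = 0.0645). In the immature neuron list, 1 of 14 promoters rose (2 adjusted over the list alone): the dendritic microtubule gene Map2 (0.78, adjusted p = 0.0478). Map2 was also the member that rose among 20 promoters of microtubule and migration genes (2 adjusted over the list alone), where Tubb2b had 0.60 (adjusted p = 0.0719). Among 18 intermediate progenitor and neurogenic genes, the RNA-binding protein gene Elavl4 rose (1.01, adjusted p = 0.00621; adjusted over the list alone 2 rose and 1 fell), and the Notch ligand gene Dll1 had 0.59 (adjusted p = 0.0618).

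Among partners of sodium channels, 2 of 9 promoters rose and 1 fell (4 and 1 adjusted over the list alone). Fgf14, which with Fgf11 and Fgf12 is among the closest relatives of Fgf13, went from 286 ± 1.67 to 498 ± 15.6 (n = 2 each, log2 fold change 0.80, SE 0.14, adjusted p = 0.0118), and the anchoring protein gene Ank2 from 357 ± 9.87 to 578 ± 23.9 (0.69, adjusted p = 0.0212). Fgf11 went down from 100 ± 7.25 to 52.0 ± 1.87 (-0.95, SE 0.21, adjusted p = 0.0385). Fgf14 and Fgf11 were also the members that changed among 25 promoters of FGF and MAPK feedback genes, with 2 risen and 1 fallen adjusted over the list alone.

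Stem cell and glial genes moved both ways. In the neural stem cell and radial glia list, 2 of 17 promoters rose (3 adjusted over the list alone): the radial glial lipid-binding protein gene Fabp7 (0.80, adjusted p = 0.0215) and the intermediate filament gene Nes (0.79, adjusted p = 0.0489). The promoters of Sox2 (0.01, adjusted p = 0.977) and Hes5 (0.04, adjusted p = 0.939) did not differ beyond the spread between replicates. In the astrocyte list, 1 of 14 promoters fell over all genes and over the list alone, that of the lipid carrier gene Apoe (-0.89, adjusted p = 0.0456). In the oligodendrocyte list, 1 of 11 fell, that of Gpr17, a receptor gene of differentiating oligodendrocyte precursors (-1.09, adjusted p = 0.0413), while Olig2 had 0.56 (adjusted p = 0.0852; 1 rose and 1 fell adjusted over the list alone). In the stress and immediate early list, 1 of 21 fell, that of the AP-1 gene Junb, from 342 ± 44.3 to 168 ± 14.8 (n = 2 each, -1.03, adjusted p = 0.00823), while Jund had -0.60 (adjusted p = 0.0539). Adjusted over the list alone, 1 stress promoter rose and 3 fell.

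The apoptosis and p53 list was lower as a group without a single called member. Of its 18 promoters 0 passed in edgeR, over all genes or over the list alone, but 2 of 18 had a higher mean in Fgf13cko and the median log2 fold change was -0.22 (camera adjusted p = 0.0326, and adjusted p = 0.749 with an estimated correlation). The estimated correlation of this list was -0.054, below the preset 0.01, so correlation between genes did not raise the latter p. Phlda3 had -0.72 (adjusted p = 0.0711) and Fas -0.57 (adjusted p = 0.117). The call ended with the replicate number as a block (adjusted p = 0.0637) and without control replicate 1 (0.0640), control replicate 2 (0.0610) or Fgf13cko replicate 2 (0.222). The other 20 lists did not pass in camera (adjusted p from 0.0756 to 0.967), and their median, mean and test differed in sign for the sodium channel, cell cycle, intermediate progenitor, astrocyte, patterning and oligodendrocyte lists.

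Of lists with 0 called promoters over all genes, the GABAergic genes had a median log2 fold change of 0.31 over 12 promoters (camera adjusted p = 0.182) and the BAF complex -0.18 over 23 (0.182), where Arid1b, a DNA-binding subunit gene, had -0.01 (adjusted p = 0.980). Notch genes had -0.14 over 18 (0.513; 1 rose adjusted over the list alone), Wnt genes -0.08 over 15 (0.511) and cell cycle genes -0.02 over 23 (0.511). In fry, the GABAergic (up) and Wnt (down) lists passed at an adjusted p = 0.0237 each and the cell cycle list (up) at an adjusted p = 0.0475. Mki67, a proliferation marker gene on the distal part of chromosome 7, had 0.75 (adjusted p = 0.0743). Housekeeping promoters had -0.07 over 17 (0.499). Of cells the cultures could also hold, microglial genes had -0.39 over 4 (0.423), meningeal fibroblast genes 0.18 over 9 (0.511), ependymal and choroid plexus genes 0.14 over 8 (0.936) and endothelial and pericyte genes 0.03 over 7 (0.967). The Neurod1 promoter had -0.66 (adjusted p = 0.577) at a low count of 22.7 ± 3.91 in controls.

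**Figure D2:**
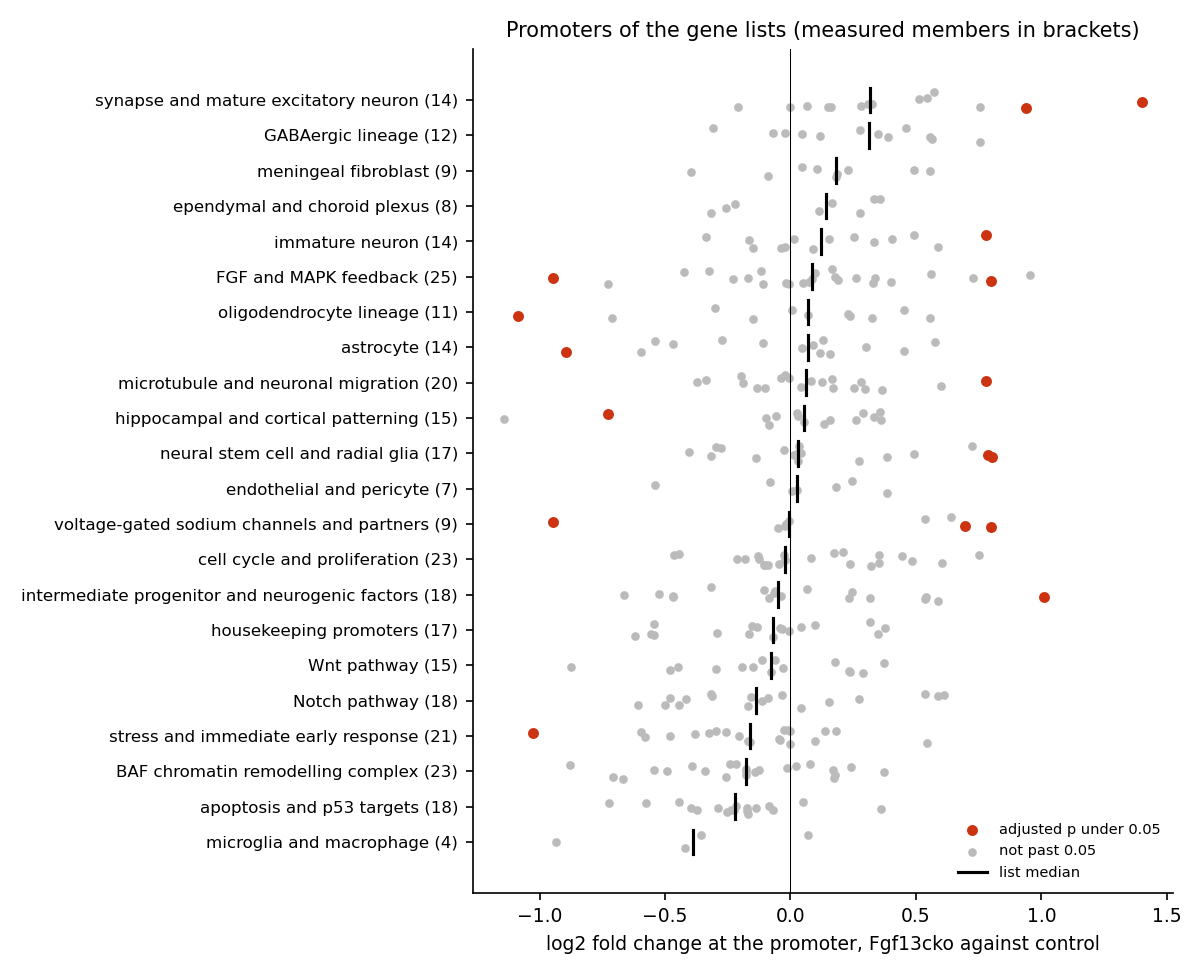
The log2 fold change of each measured promoter (x axis) is shown by gene list (y axis), with red points past an adjusted p of 0.05 and a black bar at the list median. The synaptic list has the highest median (0.32), and the apoptosis list lies at -0.22 with no red point.

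**Figure D3:**
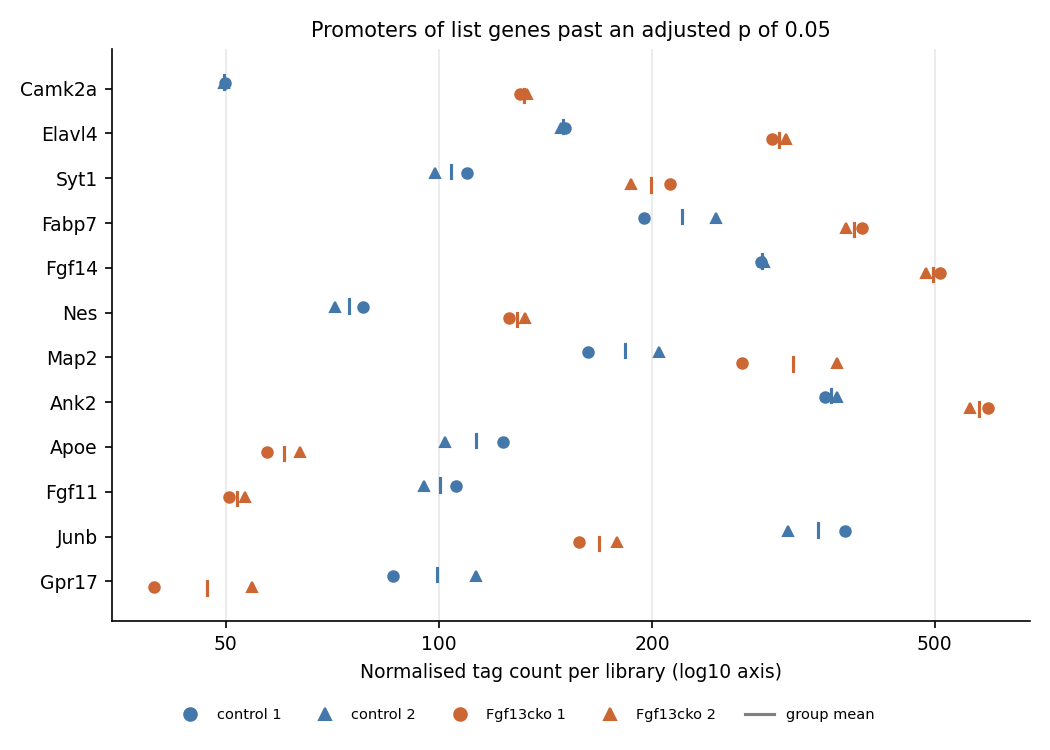
Normalised tag count per library (log10 axis) at 12 promoters of list genes past an adjusted p of 0.05, with the group mean as a bar. Camk2a (49.8 against 132) shows the largest rise and Gpr17 (99.4 against 47.0) the largest fall.

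Distal regions, summed per nearest gene, changed at single members of several lists. Among patterning and neurogenic genes, distal regions of Prox1, a transcription factor gene of dentate granule neurons, rose from 21.1 ± 7.01 to 58.3 ± 7.47 (n = 2 each, log2 fold change 1.46, SE 0.37, adjusted p = 0.0342), and those of Insm1, a gene of delaminating progenitors, rose as well (1.12, adjusted p = 0.0116). Within the limit of 20 kb, Insm1 was at -0.11 (adjusted p = 0.950). Those of the FGF feedback inhibitor genes Spry2 (1.40, adjusted p = 0.0116) and Spry4 (0.78, adjusted p = 0.0279) rose, 2 of 17 on their list. Synaptic genes had 2 of 10 risen, the neurotrophin gene Bdnf (1.18, adjusted p = 0.0191) and Nlgn1 (1.03, adjusted p = 0.0436).

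The glial and GABAergic genes included the largest falls on the lists. Distal regions of Gad2, which encodes a GABA-synthesising enzyme, fell from 247 ± 59.1 to 81.0 ± 7.52 (n = 2 each, log2 fold change -1.61, SE 0.23, adjusted p = 0.00560), while those of Maf, on the same list, rose (1.0, adjusted p = 0.0167). The region of Gfap, the astrocytic intermediate filament gene, fell from 309 ± 18.7 to 136 ± 6.44 (-1.18, adjusted p = 0.00703), 1 of 16 on the astrocyte list. The stem cell list had 2 of 17 risen, Tnc (1.26, adjusted p = 0.00690) and Fabp7 (1.16, adjusted p = 0.0254), and 2 fallen, Id4 (-1.05, adjusted p = 0.0198) and Msi1 (-0.88, adjusted p = 0.0162). The Wnt list had 1 of 20 risen, the receptor gene Fzd10 (1.33, adjusted p = 0.00988), and 1 fallen, the feedback gene Axin2 (-0.90, adjusted p = 0.0210). Lmx1a (-0.89, adjusted p = 0.0410), of the choroid plexus and patterning lists, and Trp53 (-0.88, adjusted p = 0.0291), of the apoptosis list, fell, and Eef1a1, of the housekeeping list, rose (0.71, adjusted p = 0.0342), with -0.17 within 20 kb.

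Adjusted over the list alone, the counts of distal sums were the same on these lists, except for 3 risen on the stem cell list, 2 risen and 2 fallen among patterning genes, and 1 risen among ependymal and choroid plexus genes. Distal sums of the Notch, cell cycle, BAF, microtubule, sodium channel, oligodendrocyte, stress, endothelial, meningeal and microglial lists had 0 called members. Distal regions of Olig2 had 0.64 (adjusted p = 0.0840), of Neurod1 -0.78 (adjusted p = 0.115), of Mki67 0.29 (adjusted p = 0.320), and of Sox2, Hes5, Arid1b and Fgf13 between -0.15 and 0.15. In camera 0 of the 22 lists passed (adjusted p from 0.313 to 0.928), with 1 at an unadjusted p under 0.05, and in fry 0 passed, with 5 at an unadjusted p under 0.05. The median, mean and test differed in sign for the Notch, endothelial, cell cycle, patterning, stem cell and BAF lists.

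Of 7675 tested genes, 543 rose and 272 fell at their distal regions, a rising share of 66.6%. It was 54.1% with a loess offset (560 and 476) and 54.0% with library size only (443 and 377), where the median of all genes was -0.12. The count was 191 without control replicate 1, 194 without control replicate 2, 2203 without Fgf13cko replicate 1 (1241 rose, 962 fell), 3422 without Fgf13cko replicate 2 (1766 rose, 1656 fell), and 365 within 20 kb.

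With TMM scaling, most regions that rose lay away from promoters. Of 17089 distal regions 9.48% rose and 2.24% fell, against 1.42% and 0.760% of 11712 promoter regions, a 6.69-fold difference in the rising share. By annotation, 8.77% of intronic and 8.82% of intergenic regions rose, against 1.16% of regions at start sites. The ratio of rising shares was 13.6 without control replicate 1, 18.1 without control replicate 2 and 1.45 without Fgf13cko replicate 2, and with library size only it was 0.709. The higher ratios without a control rest on few promoter regions, so they do not show a stronger difference. The falling shares were in the other order with a loess offset (4.15% of promoter and 3.57% of distal regions) and without Fgf13cko replicate 1 (14.3% and 7.01%), and were 12.2% and 20.8% without Fgf13cko replicate 2. Regions are not replicates, so no p-value is given for these shares. Over 4313 genes with both values, promoter and distal log2 fold changes correlated weakly (r = 0.132 across genes, which are not independent replicates). A set of 22 genes changed at both, against 19.3 expected from independent lists, and 19 of them had the same direction.

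**Figure D4:**
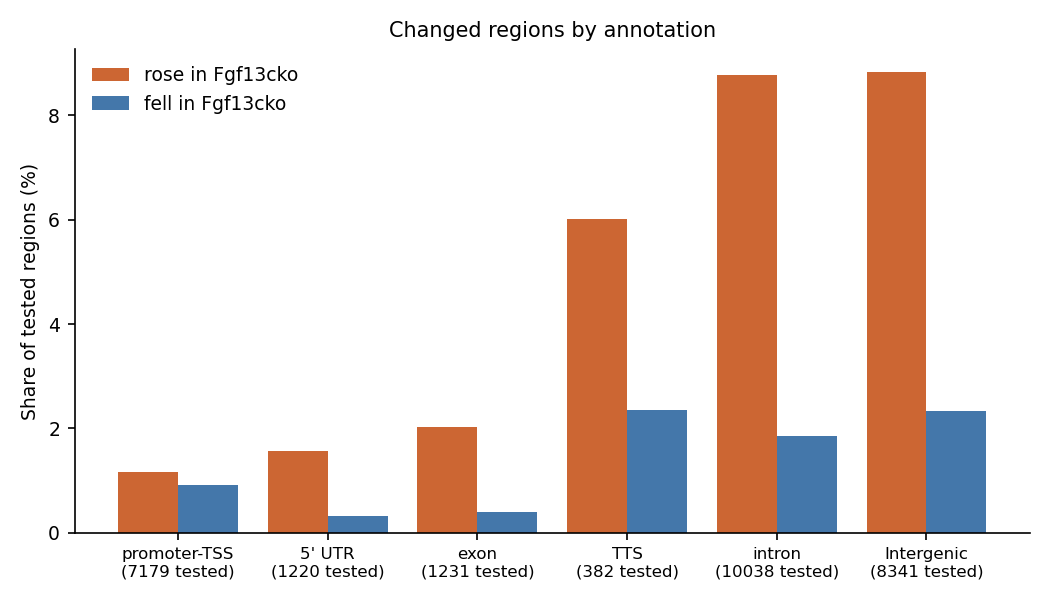
Share of tested regions that rose (orange) or fell (blue) in Fgf13cko, in percent, by the annotation class given in the count table. Intronic (8.77%) and intergenic (8.82%) regions rose more often than regions at start sites (1.16%).

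The regions of chromosome 7 from 80 Mb to its end were shifted upwards together, a segment chosen after its values were seen. Its 997 tested regions had a median log2 fold change 0.34 above that of the other autosomal and X-linked regions, and 126 of them rose (12.6%, against 5.98% elsewhere) while 9 fell. By 10 Mb bin the shift ran from 0.18 to 0.54. Chromosome 7 below 80 Mb was shifted by 0.07, with bins from -0.059 (at 20 Mb) to 0.15 (at 40 Mb). Without chromosome 7, 1658 regions rose and 427 fell.

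**Figure D5:**
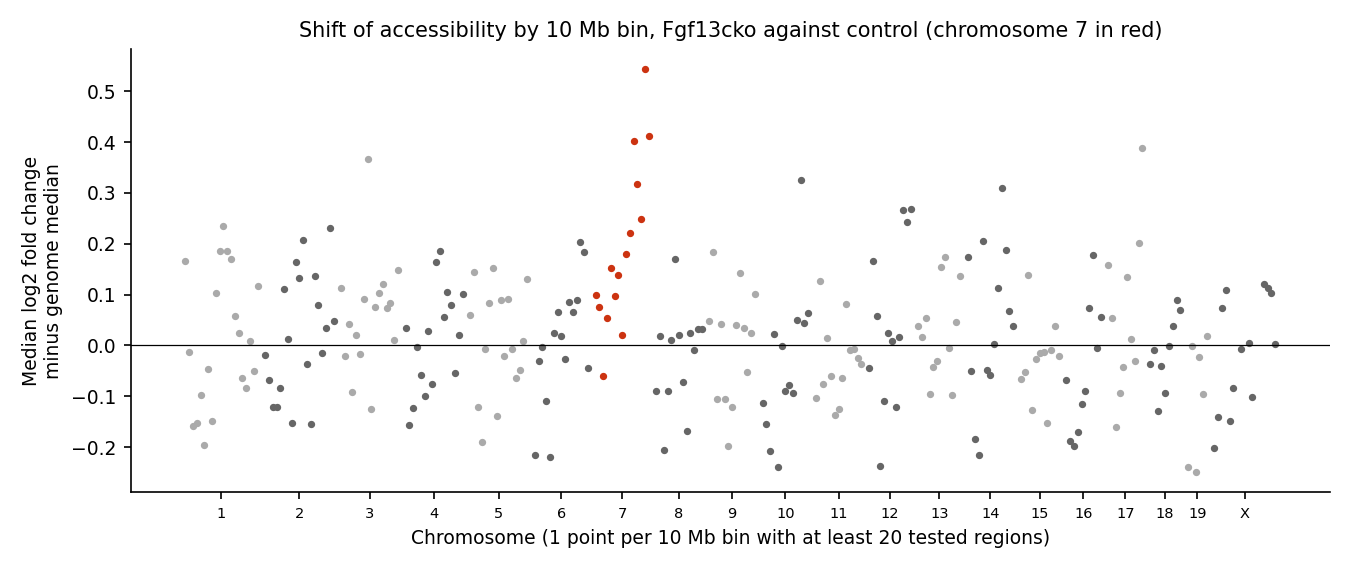
Median log2 fold change of the tested regions in each of 265 bins of 10 Mb, minus the genome median (y axis), along the chromosomes (x axis), with chromosome 7 in red. The bins of chromosome 7 from 80 Mb lie between 0.18 and 0.54.

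The peak lists held more peaks for Fgf13cko than for controls. There were 38006 and 47148 peaks in the control samples, covering 19.4 and 24.4 Mb, and 64954 and 54373 in Fgf13cko, covering 37.1 and 32.1 Mb, although the nuclear tag totals were lower in Fgf13cko (15.2 and 11.9 M, against 19 M in each control). The mean number was 1.40 times that of the controls, and 1.26 times at a -log10 q of at least 5. The median width was 429 and 436 bp in controls and 484 and 500 bp in Fgf13cko. Control peaks were overlapped by a peak of an Fgf13cko sample in 78.1% to 89.2% of cases, and Fgf13cko peaks by a control peak in 51.5% to 67.1%. Within groups, the shares were 87.7% (control 1 by control 2), 70.4% (control 2 by control 1), 71.9% (Fgf13cko 1 by Fgf13cko 2) and 85.8% (Fgf13cko 2 by Fgf13cko 1). The shares of Fgf13cko peaks overlapped by a control peak lay below all of these, and those of control peaks overlapped by an Fgf13cko peak did not. A share also depends on the number of peaks in the other list, and the control lists were shorter. These shares alone therefore do not separate a group difference from list length. With 2 samples per group, no exact test could reach a p below the threshold, and none was run on these numbers.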

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

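The fits with a loess offset or without a library and the stricter q were planned, but their use as tests of the explanations, like the other tests here except that of quartiles on chromosome 7, was chosen after the results they bear on were seen. When the peak lists of all samples were merged, 9839 regions had a peak in both Fgf13cko samples and in neither control, against 1414 with a peak in both controls and in neither Fgf13cko sample. These regions lie outside the count table, which holds the 29121 regions with a peak in all 4 samples. At a -log10 q of at least 5 the numbers were 3623 and 972. At the authors' threshold, 13433 and 5835 regions had a peak only in Fgf13cko 1 or 2, against 1617 and 4689 only in control 1 or 2. The median width was 498 bp for regions of both Fgf13cko samples and no control, and 830 bp for those of all 4 samples. The excess cannot be told apart from the larger number of peaks called per Fgf13cko sample.

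More regions rose than fell in Fgf13cko. Mitochondrial tags in the scaling are argued against as the cause, since 76.2% of the changed regions rose without the mitochondrial regions. A trend of fold change with region strength cannot be told apart from an effect of the deletion: with a loess offset on strength the rising share was 66.1% for regions and 54.1% for distal sums. In the lowest quintile of strength 0 regions rose and 11 fell, and the rising share was 52.4% in the second quintile and 84.4% in the highest. By width it was 13.8% in the lowest quintile (12 rose and 75 fell) and 91.8% in the highest. Uneven spread between the Fgf13cko libraries cannot be told apart from an effect of the deletion either. The rising share was 58.9% without Fgf13cko replicate 1 (4125 rose and 2875 fell) and 50.6% without Fgf13cko replicate 2 (5100 rose and 4986 fell), against 1786 and 472 with both. The share went down because more falls were called, and the difference of rises and falls stayed near its value with both libraries in the first of these fits and not in the other.

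The shift of chromosome 7 from 80 Mb to its end was seen at promoter regions (0.36 on the log2 scale) and distal regions (0.32). A few strongly opened regions are argued against, since the lower quartile of log2 fold change was shifted by 0.35, and so is 1 outlying library, since the smallest of the shifts over the 4 pairs of an Fgf13cko and a control library was 0.27. A higher copy number of the segment in the Fgf13cko cultures is a candidate explanation. The mean shift over its 7 bins was 0.33, and the highest of 136 runs of as many bins on the other chromosomes was 0.14. The segment was chosen for its shift, so this comparison favoured it and cannot decide between causes. Its bins ran from 0.18 to 0.54 and were not at 1 level. Shorter stretches on other chromosomes reached the range of the segment's bins. Chromosome 12 from 90 Mb had bins at 0.27, 0.24 and 0.27. The bin at 90 Mb of chromosome 17 had 0.39, and that at 70 Mb of chromosome 3 had 0.37. Base composition cannot be told apart from a higher copy number here, because no genome sequence was used. Among the other autosomes and X, each taken as a whole, chromosome 19 had the largest shift, at -0.11. Whether the segment differs through the deletion or through the mice used was not tested.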

How the results depend on the processing

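Fits without the mitochondrial regions, without chromosome 7 and without its part from 80 Mb were chosen after seeing the data; the cause of the changes below was not tested unless stated. Over the 75 called regions, promoters, distal sums and lists named, 963 of 1137 alternative values kept direction and call, 172 kept direction without passing, and 2 reversed: Eef1a1 (-0.17) and Insm1 (-0.11) distal sums within 20 kb, where fewer regions are summed. The values kept include 20 from regions called in at least 2 samples, a setting identical to the main fit. All 75 were chosen because they passed in the main fit, so the tally does not measure how stable calls are in general. Without control replicate 1, 51 of the 75 no longer passed, and without control replicate 2, 57, against 0 and 1 without Fgf13cko replicate 1 and 2. The residual spread then comes from the Fgf13cko pair or from the closely matched controls alone, and the lone sample is assumed to vary like the other group. With equal spread assumed in both groups, 33% of simulated 2-fold changes of regions were recovered at this depth with 2 samples per group.

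Leaving out each library gave 224 to 10086 changed regions, 0 to 2810 promoters, 191 to 3422 distal sums, 1 to 3 promoter lists, 0 to 1 distal lists and 1.45 to 18.1 for the ratio of rising shares. At a threshold of 0.01, 594 regions, 61 promoters and 142 distal sums passed. With library size only, 17704 regions passed and the ratio was 0.709, since the mitochondrial tags set the scale. Promoters numbered 482 with a loess offset, 491 with a mean of at least 50 counts and 142 in the Wald test, and distal sums 365 within 20 kb. Promoter lists past 0.05 numbered 0 with an estimated correlation and 4 in fry (apoptosis, GABAergic and Wnt, each at 0.0237, and cell cycle, at 0.0475, but not the synaptic list, at 0.0645), and 1 distal list passed with a loess offset. Control peaks overlapped by Fgf13cko peaks fell from 83.9% to 63.2% when 50% of both peaks had to overlap. Keeping regions called in at least 2 samples removed none, so this alternative shows nothing.

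Values at the Fgf13 locus, and some values near 0, changed sign or size. With library size only, the Fgf13 regions at 59133646, 59178885, 59241102 and 59566138 had 0.78, 1.80, 0.42 and 0.98. The region at 59566138 had -0.11 with a loess offset, -0.045 with a mean of at least 50 counts, -0.0065 in limma-voom, -0.00081 without the mitochondrial regions and -0.34 to 0.31 with a library left out, and that at 59178885 had 0.64 to 1.08. With a library left out, promoters ranged from -0.20 to 0.15 (Fgf13), -0.36 to 0.27 (Arid1b), -0.13 to 0.18 (Sox2) and -0.21 to 0.26 (Hes5), and distal sums from -0.40 to 0.23 (Arid1b), -0.034 to 0.33 (Fgf13) and -0.55 to 0.19 (Sox2). The Sox2 promoter had -0.0047 with a loess offset, and without chromosome 7 the Fgf13 and Arid1b promoters had 0.0037 and 0.0074.

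With the replicate number as a block, 2808 regions, 402 promoters, 1007 distal sums, 1 promoter list and 0 distal lists passed; the block ended the call of the apoptosis list and no other named call. The numbers are not known to pair the samples: the difference of control 1 and 2 correlated at -0.232 with that of Fgf13cko 1 and 2 across regions. The motif alternatives (regions of the loess fit, the central part of each region) were not run, since no genome sequence was used.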

Other observations

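The tests of the cytokine response and pan-reactive lists, and the use of the planned astrocyte list test as a test of the hypothesis, were chosen after the results they bear on were seen. Several of the fallen regions and promoters were assigned to genes induced by cytokines in glia, a group that was not among the lists fixed beforehand. The distal sum of Nfkbiz fell from 75.8 ± 13.5 to 12.8 ± 0.628 (n = 2 each, log2 fold change -2.57, adjusted p = 0.00467). This sum holds the same tags as the intergenic region nearest to Nfkbiz named above (-2.45), 75769 bp from the start site. The 2 values are therefore not separate evidence. Distal regions of Socs1, a feedback inhibitor gene of cytokine signalling, fell from 58.3 ± 1.21 to 12.8 ± 11.3 (-2.12, adjusted p = 0.0305). The promoters of Nfkbiz (0.14, adjusted p = 0.648) and Socs1 (-0.12, adjusted p = 0.741) did not pass. Against the direction of the falls, distal regions of Stat3 rose (1.11, adjusted p = 0.0353), as did the promoter of the interferon-induced gene Ifi44l (1.51, adjusted p = 0.00448).

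A list of 22 cytokine response genes of the JAK-STAT and NF-kB pathways had 18 measured promoters, of which 0 rose and 2 fell, with 3 of 18 higher in Fgf13cko (camera adjusted p = 0.00171, and adjusted p = 0.149 with an estimated correlation). Junb and Osmr, the oncostatin M receptor gene, were the promoters that fell, and Osmr, first seen in this test, went from 128 ± 4.14 to 70.9 ± 11.8 (n = 2 each, -0.85, adjusted p = 0.0456). A list of 13 pan-reactive astrocyte genes had 8, with 0 risen and 2 fallen (adjusted p = 0.00609, and 0.160 with an estimated correlation). At distal regions neither list passed in camera (adjusted p = 0.332 and 0.465). Adjusted over the list alone, 3 distal sums of the cytokine list rose and 4 fell. Of the cytokine list 1 gene, and of the reactive list 3 genes, stand on the lists fixed beforehand.

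A hypothesis is that promoters of cytokine response genes were less accessible in Fgf13cko. The lists were written after some members had been seen, so these were left out (Junb, Nfkbiz, Socs1, Serpina3n and Gfap). The remaining 15 promoters of the cytokine list had a median of -0.20, and 13 of 15 were lower (camera p = 0.00462, direction down, and p = 0.151 with an estimated correlation). A median of this size is not particular to cytokine genes. Promoter medians of the lists fixed beforehand ran from -0.39 (microglial, 4 promoters) to 0.32 (synaptic), with -0.22 for apoptosis, -0.18 for BAF and -0.16 for stress genes. Single regions at start sites had a median of -0.097. At distal regions the remaining 11 members of the cytokine list gave a camera p = 0.997 with the preset correlation, direction up, but the members left out include the distal falls of Nfkbiz and Socs1, so this value decides nothing. The remaining 7 promoters of the reactive list gave a camera p = 0.132 with the preset correlation, which leaves that list open. A lower share of astrocytes may contribute and cannot be told apart here. The astrocyte promoters went both ways (camera p = 0.624 with the preset correlation), while that of Apoe fell. The region of Gfap fell too, but it lies just beyond the promoter window and is not in that test.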
